A study of Arabidopsis thaliana with 6 samples.

How the data were processed

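The series holds 6 expression arrays of Arabidopsis suspension cells with an estrogen-inducible ATHB8 fusion, 3 from cells with 5 µM estrogen for 24 h and 3 from cells without it. Per the labels, total RNA was labelled as sense-strand DNA and hybridised to a whole-transcript GeneChip. The deposited values are log2 expression for each row of the array, made by the authors with Affymetrix Expression Console 1.3 per the submitters' processing notes. The background correction, normalization and summarization are not stated, nor is a genome build, so the values were used as deposited and no coordinates are given. No line without the transgene and no treatment with estrogen alone of such a line is among the samples.

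Rows were matched to genes by the names in the array's own annotation, and a current RefSeq gene table served only to pair locus codes with symbols. Of the 16722 rows that name a single gene, 14896 give only a locus code, and 139 named genes have no current RefSeq entry. The 146 genes with several rows were represented by the row with the highest mean signal over all 6 arrays. The 20927 rows without a gene name were tested with the rest, but no gene was assigned to them. Of all rows, 7132 share all 6 values with another row, and 6976 of these have no gene name.

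The induced and uninduced arrays were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at their default settings, no block and no filter, two-sided, over all 38408 rows with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given with a ± and SE come from this fit. An exact permutation test of 3 arrays against 3 can reach no p below 0.10, so single genes rest on the model across all rows. Nothing in the labels says that the replicates are separate cultures; if they are not, the p-values measure only the spread between these samples, which may be technical. The replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means, which gave 0.633, 0.268 and 0.248 across rows, which are not independent replicates. All 3 lay above a threshold of 0.1 set for this check. A fit with the replicate number as a block therefore stands beside the results where it changes a call or a count. The cross-numbered pairs among replicates 2 and 3 gave 0.244 and 0.260, about as much as the same-numbered ones. The check therefore sets the replicate 1 arrays apart and does not show that the numbers pair replicates 2 and 3.

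Named genes follow a rule fixed before the data were examined: ATHB8, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, and up to 4 members of each gene list with the smallest p, or any member of the HD-ZIP III and brassinosteroid lists. Genes named outside this rule are said to be chosen after their values were seen. Gene lists were tested with camera of limma at its preset correlation of 0.01 and again with an estimated correlation. Benjamini-Hochberg adjustment ran over the 34 lists with at least 4 measured members. With an estimated correlation camera also tests on the 4 residual degrees of freedom. A call lost in that setting therefore need not be due to correlation between members. Of 27 lists fixed before the data were examined 1, the auxin-responsive genes, had enough measured members. The other 33 lists were drawn up from the symbols on the array after this gap was seen and before any difference between the groups was computed. Matched random lists (10000 per list) were drawn within 20 bins of mean signal.

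The fits were tested on simulated data of 38408 rows with 200 changed genes, 50 at each size. The simulated values held the offset of replicate 1 and the spread left after it, with no other replicate effect and no equal values. They therefore favour the fit with replicate 1 against the rest as a block and cannot rank the fits. With no block the test found 0 of 50 genes changed 1.5-fold, 15 changed 2-fold, 32 changed 3-fold and 38 changed 5-fold, with 0 false calls among 85. With the replicate block it found 0, 0, 18 and 38, and with replicate 1 against the rest as a block 12, 31, 38 and 44, with 4 false calls among 129. The alternatives tried were other normalizations, filters on low signal, variance priors, array weights, the replicate block, the mean of all rows of a gene, other thresholds and set tests, and leaving out each array in turn. Alternatives added after seeing the data were a block for replicate 1 against the rest, replicates 2 and 3 alone, a fit on distinct rows, and a fit on rows that name a single gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.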

Results

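The arrays measured RNA from Arabidopsis suspension cells, grown in the dark, that carry a fusion of ATHB8 and green fluorescent protein under an estrogen-inducible promoter. ATHB8 is a transcription factor of the class III homeodomain leucine zipper family (HD-ZIP III), known for its expression in procambium, the tissue from which xylem and phloem form. The 3 induced arrays hold cells that had received 5 µM estrogen for 24 h, and the 3 uninduced arrays hold cells sampled at the same time without it. The series set out to find genes that act downstream of ATHB8. Each array gives a log2 signal for 38408 rows, of which 16722 name a single gene, 759 name several genes and 20927 carry no gene name. The named rows cover 16550 genes. The median log2 signal was 5.95 in both replicate 1 arrays and lay between 5.80 and 5.84 in the other 4 arrays. The replicate 1 arrays held exactly the same value in 12229 rows (31.8%), against at most 23 rows in any other pair of arrays. These equal values made up 57.5% of the rows in the second lowest decile of signal and 9.16% in the highest decile. The first principal component (41.4% of the variance) set both replicate 1 arrays apart from the other 4, and the second (26.0%) set the induced arrays apart from the uninduced ones. The number of arrays, 3 in each group, limits the precision of every value.

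**Figure D1:**
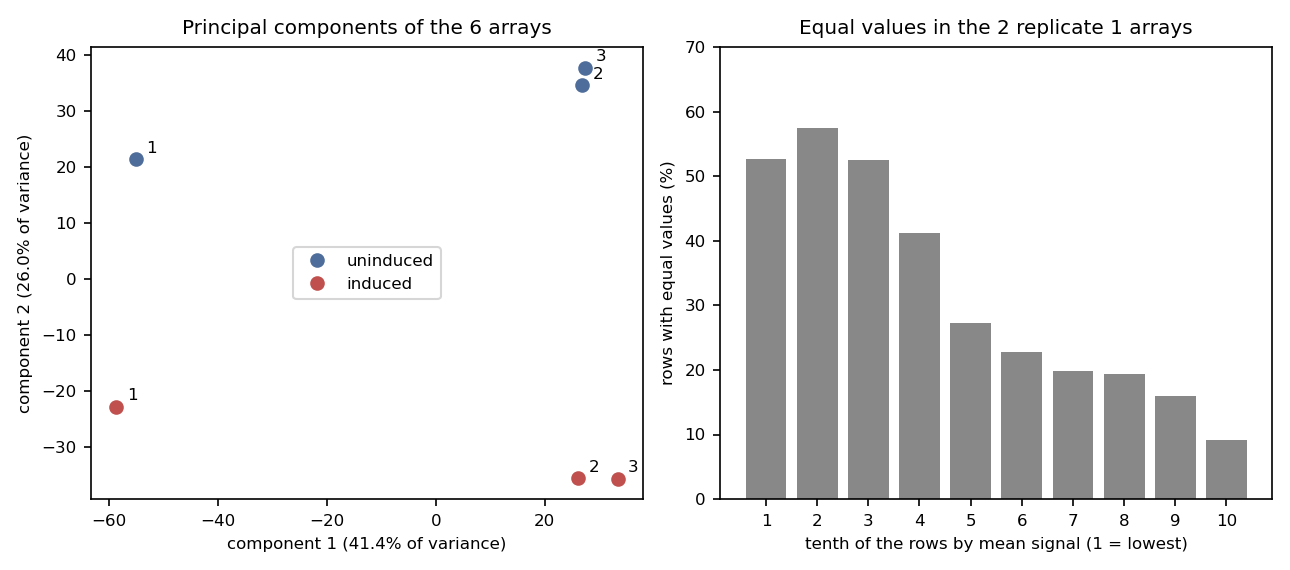
Left, each array on principal components 1 and 2 of the log2 signal, coloured by group and numbered by replicate; right, the percent of rows with exactly equal values in both replicate 1 arrays, by decile of mean signal. Both replicate 1 arrays lie at the low end of component 1, and equal values fall from 57.5% of rows in the second lowest decile to 9.16% in the highest.

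The genes that rose most in the induced cells included a sugar carrier, a peroxidase, an efflux carrier and proteins that act on the cell wall. SAG29 (AT5G13170), a sugar carrier also known as SWEET15, rose 11.7-fold, from a log2 signal of 8.37 ± 0.17 to 11.92 ± 0.11 (SD, n = 3 per group). AT4G02830 had the largest log2 difference of the named genes, 3.94 (15.4-fold), from 3.96 ± 0.45 to 7.90 ± 0.13 (SD, n = 3 per group). It is among the 9 of the 12 largest rises that have only a locus code and no symbol here. AT1G71695, a class III peroxidase, rose by 3.32 ± 0.18 on the log2 scale (SE), and AT5G17700, an efflux carrier of the MATE family, by 3.07 ± 0.16. TBL38 (AT1G29050), of a family that includes acetyltransferases of wall polysaccharides, rose by 2.80 ± 0.31, and the pectin lyase-like gene AT3G53190 by 2.76 ± 0.16. TRI (AT2G29330), a homologue of tropinone reductase, rose by 2.72 ± 0.19. The remaining genes among the 12 largest rises were AT3G08490, AT1G63520, AT1G22065, AT3G46880 and AT3G13980, with log2 differences from 2.66 to 3.60. Except for SAG29, the uninduced means of these 12 genes lay below that of the median row, between percentiles 13.8 and 43.5 of all rows and at percentile 27.5 for AT4G02830. No background level was analysed here, so their folds and the order of these genes rest on uninduced signals not shown to lie above background. By the rule that chose these 12 genes, all 3 induced arrays lay above all 3 uninduced arrays, with limma adjusted p between 7.9e-04 and 0.0293. All 12 also passed with the replicate number as a block, and 11 passed in replicates 2 and 3 alone, a fit chosen after seeing the data. Leaving out an array kept 12 of these calls without induced replicate 1, 9 without induced replicate 2, 9 without induced replicate 3, 10 without uninduced replicate 1, 9 without uninduced replicate 2 and 8 without uninduced replicate 3. The calls that ended were those of TBL38 and AT3G13980, which passed in 1 of the 6 fits each, AT1G22065, which passed in 2, and TRI, which passed in 5.

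The 12 largest falls were each smaller than any of the 12 largest rises and included a remorin, a MADS-box gene and a Dof transcription factor. AT2G46850 fell most, by 1.71 ± 0.23 on the log2 scale (SE, n = 3 per group), from 6.11 to 4.40. AT5G48130, of the NPH3 family known from blue light signalling, fell by 1.70 ± 0.15, and the remorin gene AT1G67590, of a family of plasma membrane proteins, fell by 1.59 ± 0.12. AT1G23160, of the GH3 family, whose members join amino acids to auxin and jasmonate, fell by 1.45 ± 0.10. The MADS-box gene AGL78 (AT5G65330) fell by 1.39 ± 0.20 and AT2G28510, a Dof transcription factor, by 1.39 ± 0.17. The remaining genes among the 12 largest falls were AT1G21326, AT1G76620, AT1G66930, At17.1 (AT2G01340), AT4G18335 and AT1G77530, with log2 differences from -1.53 to -1.26. By the rule that chose these 12 genes, all 3 induced arrays lay below all 3 uninduced arrays, and the limma adjusted p lay between 0.00459 and 0.0434. With the replicate block 10 of the 12 passed, without AT1G21326 (adjusted p = 0.0716) and AT1G77530 (0.0988). Quantile normalization ended the calls of AT1G21326 (0.0538) and At17.1 (0.0641), as did median subtraction (0.0504 and 0.0610). Leaving out an array kept 8 of these calls without induced replicate 1, 3 without induced replicate 2, 4 without induced replicate 3, 6 without uninduced replicate 1, 4 without uninduced replicate 2 and 1 without uninduced replicate 3. AT1G23160 passed in all 6 of these fits, and AT2G46850 (adjusted p 0.0542 to 0.181) and AGL78 (0.0534 to 0.214) passed in none. In replicates 2 and 3 alone 0 of the 12 passed in limma, with adjusted p from 0.0530 to 0.162 and 12 at an unadjusted p under 0.05.

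**Figure D2:**
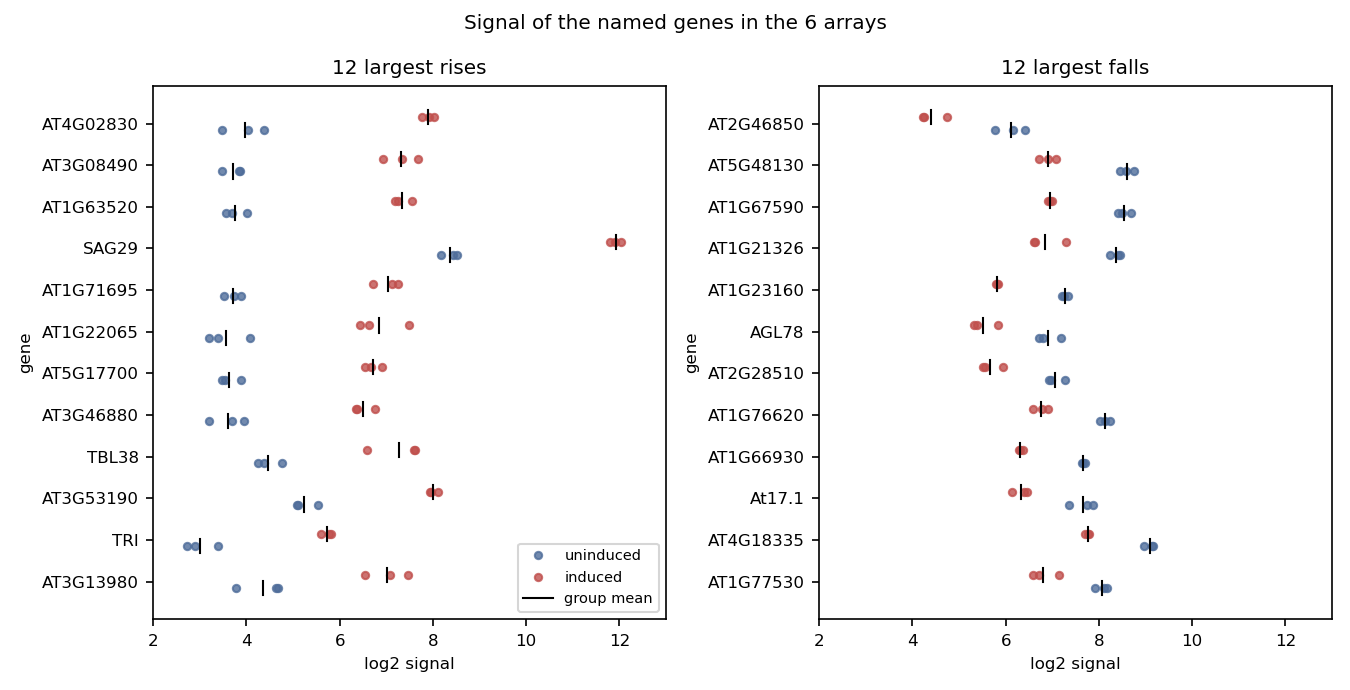
Log2 signal (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall (vertical axis), with a point for each of the 3 induced and 3 uninduced arrays and a line at each group mean. In all 24 genes the points of the groups do not overlap, as the rule that chose them requires. The rises reach 3.94 log2 units while the falls reach -1.71.

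Over all named genes, 119 rose and 68 fell in the induced cells, 187 of 16550 at an adjusted p under 0.05. Of these, 92 rose and 35 fell by at least 2-fold, and 1443 genes had an unadjusted p under 0.05. Over all 38408 rows, 369 changed, 243 upward and 126 downward, and 179 of them carry no gene name. The 8 largest rises of any row belong to rows without a gene name, which hold 6 distinct sets of values. Row 13492619 rose by 7.22 ± 0.20 on the log2 scale (SE, n = 3 per group) from 5.78, and row 13545421 rose by 6.52. In all 187 changed genes the groups did not overlap. Over all rows they did not overlap in 12.2%. The 10% that chance gives holds only for interchangeable arrays without equal values. The 12229 rows with equal values in both replicate 1 arrays could not count as apart, so the 12.2% was not judged against it. With the replicate number as a block 121 genes changed, 82 upward and 39 downward, and 188 of the 369 rows stayed called. The count was 83 genes without induced replicate 1, 35 without induced replicate 2, 38 without induced replicate 3, 67 without uninduced replicate 1, 36 without uninduced replicate 2 and 26 without uninduced replicate 3. Chosen after seeing the data, a fit with replicate 1 against replicates 2 and 3 as a block called 532 genes, 259 upward and 273 downward, and replicates 2 and 3 alone gave 40 genes, 40 of them upward.

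Among the vascular genes CLE41 fell in the induced cells; it encodes the precursor of a peptide made in phloem that keeps procambium dividing. CLE41 (AT3G24770) fell by 1.04 ± 0.14 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0393). CLE44, which encodes the same peptide, differed by -0.40 ± 0.20 (adjusted p = 0.751), and LHW, a partner of the vascular regulator TMO5, by 0.31 ± 0.10 (0.403). Of 10 genes for CLE peptides 7 lay lower and 3 higher, and the list was not called (camera adjusted p = 0.604). CLE22 differed by 1.54 ± 0.29 (limma adjusted p = 0.0847), from an uninduced mean of 3.27. It passed with replicate 1 against the rest as a block (0.0378) and in replicates 2 and 3 alone (0.0478), not with the replicate block (0.102). Of 12 vascular genes with a named row 1 fell, and the list as a whole was not called (adjusted p = 0.717). BRL1, a brassinosteroid receptor of vascular cells, differed by -0.73 ± 0.11 (adjusted p = 0.0509), with all 3 induced arrays below all 3 uninduced ones. Of the 7 brassinosteroid genes with a named row, BRH1 differed by 0.48 ± 0.16 (0.424) and EXO by -0.38 ± 0.18 (0.70), and the list was not called (0.702). In the HD-ZIP III family itself PHV differed by -0.02 ± 0.11 (adjusted p = 1.0), and HAT2, a reported target of the family, by 0.46 ± 0.17 (0.510). PHV was the only 1 of 5 HD-ZIP III genes, and HAT2 the only 1 of 14 reported targets, measured under its name. Of 21 xylem regulators and 10 enzymes of brassinosteroid synthesis 0 were measured under their name. ATHB8 has no row under its name. The rows without a gene name were tested but assigned to no gene, so no value is given for ATHB8. A rise of ATHB8, planned as a check on the labels, could therefore not be read. With replicate 1 against the rest as a block, chosen after seeing the data, BRL1 (adjusted p = 0.0291) and HAT2 (0.0396) passed, and with the replicate block neither did (0.0654 and 0.0969). The fall of CLE41 did not pass with the replicate block (adjusted p = 0.0734) or in replicates 2 and 3 alone (0.163), nor without induced replicate 1 (0.108), 2 (0.189) or 3 (0.181) or without uninduced replicate 1 (0.105), 2 (0.118) or 3 (0.133). Of the 299 genes in the lists fixed before the data were examined 39 were measured under their name, of which 1 fell and 0 rose in limma, with 4 higher and 10 lower at an unadjusted p under 0.05. When adjusted over the list alone 12 passed, of which 4 were the only measured member of their list, so that nothing was adjusted, 7 stood in lists with 2 or 3 measured members, and 1 in a list with 4 or more.

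Genes that auxin raises lay lower in the induced cells as a group. The median log2 difference of the 8 measured members was -0.38, and 6 of the 8 lay lower in the induced arrays (camera adjusted p = 0.0425; adjusted p = 0.320 with an estimated correlation). WES1 (GH3.5, AT4G27260), which conjugates auxin to amino acids, differed by -0.42 ± 0.10 (SE, n = 3 per group; adjusted p = 0.189), GH3.1 by -0.33 ± 0.13 (0.529), the auxin repressor IAA30 by -0.90 ± 0.30 (0.413) and LBD29, a regulator of lateral roots, by -0.63 ± 0.26 (0.593). In the same-numbered pairs 1, 2 and 3 IAA30 differed by -1.77, -0.53 and -0.40, and LBD29 by -0.20, -0.26 and -1.42. Of the 8 genes 0 passed over all rows in limma, 3 lay lower at an unadjusted p under 0.05, and WES1 passed when adjusted over the list alone (adjusted p = 0.0467). YUC4, an enzyme of auxin synthesis, differed by 0.75 ± 0.15 (adjusted p = 0.107). With replicate 1 against the rest as a block YUC4 passed (0.0302), as did LBD16, a regulator of lateral roots chosen after its values were seen, at -0.55 ± 0.25 (0.0276), and with the replicate block neither did (0.0794 and 0.0772). The call of the group ended without induced replicate 1 (adjusted p = 0.17) or uninduced replicate 1 (0.125), in replicates 2 and 3 alone (0.0807), with median subtraction (0.0534) and array weights (0.0998), and with fry (0.0576) and camera on ranks (0.121). Over all alternatives run its adjusted p lay between 0.0017 and 0.320.

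Genes of mitosis and cytokinesis lay lower in the induced cells as a group, and genes of DNA replication were called lower in the reported fit but not in most fits that left out an array. Lists fixed before the data were examined held 15 mitosis genes, of which 2 were measured under their name. They also held 13 genes of DNA replication and G1 to S, of which 1 was measured. The lists tested here were drawn up later from the symbols on the array. Of 13 mitosis genes 12 lay lower, with a median log2 difference of -0.28 (camera adjusted p = 5.7e-04; adjusted p = 0.432 with an estimated correlation). KINESIN-12B, a motor of the plane where new walls form, differed by -0.59 ± 0.10 (SE, n = 3 per group; adjusted p = 0.0599), the mitotic kinase AUR1 by -0.42 ± 0.10 (0.175) and BUBR1, of the spindle checkpoint, by -0.46 ± 0.14 (0.326). The median of the mitosis genes was -0.25, -0.32 and -0.34 in the same-numbered pairs 1, 2 and 3, and 10 of the 13 lay lower in all 3 pairs. Of 12 replication genes 10 lay lower, with a median of -0.15 (camera adjusted p = 0.0425; adjusted p = 0.320 with an estimated correlation). Among them TOPII, a DNA topoisomerase, differed by -0.49 ± 0.16 (adjusted p = 0.360), PRL, the helicase subunit MCM7, by -0.26 ± 0.10 (0.523) and the polymerase subunit POLA3 by -0.26 ± 0.10 (0.577). In limma 0 of these 25 genes passed over all rows, with 4 mitosis and 3 replication genes lower at an unadjusted p under 0.05. KINESIN-12B passed with replicate 1 against the rest as a block (0.0265) and not with the replicate block (0.0716). The call of the mitosis genes held without each array in turn (4.4e-04 to 0.0205) and ended with fry (0.0731). That of the replication genes ended without induced replicate 1 (adjusted p = 0.17) or 3 (0.0627), without uninduced replicate 1 (0.125), 2 (0.133) or 3 (0.0503), in replicates 2 and 3 alone (0.0807), with quantile normalization (0.0823), median subtraction (0.0534), the 25th percentile filter (0.0671) and array weights (0.0831), and against matched random lists (0.0731).

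Jasmonate and defence genes with a named row lay lower in the induced cells as a group. Lists fixed before the data were examined held 8 jasmonate and wounding genes and 7 pathogen defence genes. Of these 0 were measured under their name, so the shift is that of other genes. Of 25 jasmonate and defence genes 20 lay lower, with a median log2 difference of -0.21 (camera adjusted p = 0.0169; adjusted p = 0.320 with an estimated correlation). In limma 0 of the 25 passed over all rows, with 4 lower and 0 higher at an unadjusted p under 0.05. The transcription factor WRKY6 differed by -0.55 ± 0.10 (SE, n = 3 per group; adjusted p = 0.0742), the zinc finger protein STZ by -0.69 ± 0.12 (0.0789) and the ubiquitin ligases PUB23 and PUB22 by -0.55 ± 0.13 (0.193) and -0.51 ± 0.15 (0.314). With replicate 1 against the rest as a block WRKY6 (0.0282), STZ (0.0455) and PUB23 (0.0321) passed, and with the replicate block they did not (0.0792, 0.0871 and 0.0794). The median was 0.00, -0.30 and -0.11 in the same-numbered pairs 1, 2 and 3, and 11 of the 25 genes lay lower in all 3 pairs. The replicate 1 arrays held equal values in 7 of the 25 genes. Without induced replicate 2 the median was -0.05 (adjusted p = 0.0411), and over the rows at or above the median signal it was -0.38 (0.00219). The call held without each array in turn and in replicates 2 and 3 alone (0.0133), and ended with fry (0.0731).

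Genes of autophagy lay higher in the induced cells as a group, and in the TBL family TBL38 rose while the shift of the family was lost under most alternatives. Of 10 autophagy genes 9 lay higher, with a median log2 difference of 0.24 (camera adjusted p = 0.0306; adjusted p = 0.320 with an estimated correlation). In limma 0 of the 10 passed over all rows, with 1 higher and 0 lower at an unadjusted p under 0.05. The ATG8 proteins, which build the autophagosome membrane, gave differences of 0.37 ± 0.13 for ATG8F (SE, n = 3 per group; adjusted p = 0.429), 0.28 ± 0.13 for ATG8C (0.659) and 0.49 ± 0.24 for ATG8E (0.719). Of the 23 TBL genes 14 lay higher, with a median of 0.08 and a mean of 0.23 (camera adjusted p = 0.0425; adjusted p = 0.320 with an estimated correlation). TBL19 differed by 1.02 ± 0.19 (adjusted p = 0.0911) and TBL39 by 0.34 ± 0.11 (0.393). The replicate 1 arrays held equal values in 1 of the autophagy genes and in 11 of the TBL genes. The call of the autophagy genes held in replicates 2 and 3 alone (0.0133) and ended without induced replicate 1 (median 0.10, adjusted p = 0.141) or uninduced replicate 2 (0.16, 0.0662), over the rows at or above the median signal (0.0878) and with fry (0.0925). Without uninduced replicate 3 the median of the autophagy genes was 0.14 (0.0452). The call of the TBL family ended with the replicate block (0.0555), quantile normalization (0.0638), median subtraction (0.0632), the 25th percentile filter (0.0884) and array weights (0.0800), in replicates 2 and 3 alone (0.0807), with fry (0.0907) and camera on ranks (0.121), and against matched random lists (0.111). It also ended without induced replicate 1 (median 0.03, adjusted p = 0.106) or 3 (0.08, 0.0753) and without uninduced replicate 1 (0.12, 0.129) or 2 (0.06, 0.133), and without uninduced replicate 3 its median was 0.13 (0.0411). The call of TBL38 itself ended without each array but induced replicate 1: without induced replicate 2 (0.122) or 3 (0.109) and without uninduced replicate 1 (0.0757), 2 (0.0986) or 3 (0.130). Of the 34 lists tested 6 were called, 4 lower and 2 higher in the induced cells, against 2 without induced replicate 1 and 3 without uninduced replicate 1. With an estimated correlation camera called 0 of the 34, with 5 at an unadjusted p under 0.05. That correlation was negative for the auxin, replication, autophagy and TBL lists, so correlation between members did not end those calls. Fry, which asks whether the genes of a list move the same way on balance, called 1, the replication genes.

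**Figure D3:**
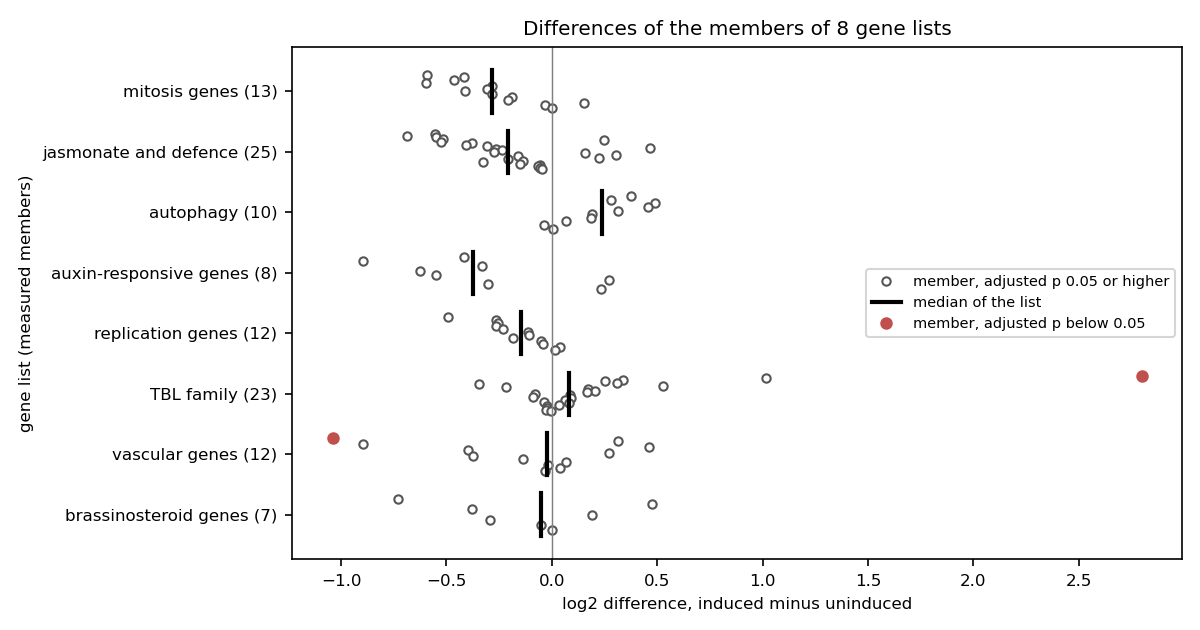
Log2 difference, induced minus uninduced (horizontal axis), of each measured member of 8 gene lists (vertical axis), with a line at each list's median; filled points have an adjusted p under 0.05. Of the mitosis genes 12 of 13 lie below 0, and the filled points are TBL38 and CLE41.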

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

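The fits on replicate 1 against the rest, on replicates 2 and 3 alone, on distinct rows and on rows naming a single gene were chosen after seeing the data. Against 369 rows and 187 genes, the counts were 827 and 417 for rows at or above the median signal, 691 and 350 at or above the 25th percentile, 706 and 355 with a trend and robust prior, 977 and 487 with array weights, 242 and 121 with the replicate block, 88 and 47 at an adjusted p under 0.01, 166 and 82 with treat at 1.2-fold, 1106 and 532 with replicate 1 against the rest as a block, 80 and 40 in replicates 2 and 3 alone, and 613 and 317 on distinct rows. On rows naming a single gene 351 genes changed. Beyond the construction of these settings (fewer rows or arrays, a stricter test) the cause was not tested. Without each array in turn the counts ran from 48 to 167 rows and from 26 to 83 genes, on fewer arrays. Quantile normalization, median subtraction, the mean of all rows of a gene and the 2-fold minimum kept both counts within 1.5 times. Against 6 lists, median subtraction, array weights and replicates 2 and 3 alone called 3 each, the estimated correlation 0 and fry 1, and leaving out each array called 2 to 6 (2 without induced replicate 1, 3 without uninduced replicate 1); the cause was not tested. All other settings called 4 to 7 lists. The difference of PHV turned positive with array weights (5.45e-04), and in replicates 2 and 3 alone (0.0374), and ran from -0.0720 to 0.0250 without each array in turn, and the cause was not tested. None of the 39 named genes and rows that passed turned in sign in the 18 fits run for each. Of 36 followed genes that had not passed, 9 did with replicate 1 against the rest as a block. Under the replicate block 30 passed and 9 did not, quantile normalization and median subtraction kept 34 each, and leaving out each array kept 12 to 27. Where a filter removed a gene it gave no value, in 25 cases for the named genes. The alternatives planned for ATHB8 were not run, since it has no named row. Equal values in replicate 1, most frequent at low signal, limit what that pair shows for genes of low signal.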

Other observations

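Of 63 genes of the plastid genome 56 lay higher in the induced arrays, with a median log2 difference of 0.04, and the list was not called (camera adjusted p = 0.0843; 0.805 with an estimated correlation). It was called with the replicate block (0.0203), with replicate 1 against the rest as a block (0.04997), with a trend and robust prior (0.0172), with camera on ranks (0.00284), against matched random lists (0.00748), without induced replicate 3 (0.0120, median 0.07) and without uninduced replicate 2 (0.00245, median 0.08). With median subtraction 49 of 63 lay higher, with a median of 0.03 (0.191), and the list was not called by fry (0.507), in replicates 2 and 3 alone (0.251) or without induced replicate 1 (0.17) or 2 (0.771, median 0.02) or uninduced replicate 1 (0.395) or 3 (0.647, median 0.01), and the adjusted p ran from 0.00245 to 0.805 over all alternatives. Of 15 nuclear photosynthesis genes 11 lay higher and the list was not called (adjusted p = 0.227); RCA, the activase of Rubisco, differed by 0.59 ± 0.14 (SE, n = 3 per group; adjusted p = 0.172). Glutathione transferases, enzymes of detoxification, lay higher in 4 of 15 genes and were not called (0.276), with GSTL3 at 0.62 ± 0.12 (0.109) and GSTU25 at -0.81 ± 0.20 (0.190; 0.0160 with replicate 1 against the rest as a block and 0.0596 with the replicate block). The 28 lists not called had adjusted p from 0.0843 to 0.951.

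Several large families held members that changed while the family as a list was not called. Among 32 serine carboxypeptidase-like genes SCPL34 rose by 1.19 ± 0.12 on the log2 scale (SE, n = 3 per group; adjusted p = 0.0150) and scpl35 fell by 1.2 ± 0.16 (0.0337). AGL54, a MADS-box gene, rose by 1.37 ± 0.17 (0.0275), the vacuolar fructose carrier SWEET17 by 0.62 ± 0.09 (0.0489) and the cytochrome P450 gene CYP71B29 by 0.98 ± 0.13 (0.0339), and UGT72E1, a glucosyltransferase of lignin precursors, fell by 0.88 ± 0.11 (0.0268). The SWEET list was drawn from symbols and left out SAG29 (SWEET15); with SAG29 added, a choice made after seeing the data, 2 of 15 carriers rose and the list was not called (camera adjusted p = 0.148, against 0.696 without it). Of these SCPL34 (0.0517), AGL54 (0.0636), SWEET17 (0.0673) and UGT72E1 (0.0614) did not pass with the replicate block. Quantile normalization ended the calls of CYP71B29 (0.0638), scpl35 (0.0633) and SWEET17 (0.0715), as did median subtraction (0.0669, 0.0579 and 0.0740), and the trend and robust prior ended that of SWEET17 (0.0635). In replicates 2 and 3 alone all 6 failed to pass (0.0849 to 0.145), and without each array in turn only SCPL34 passed, and only without induced replicate 1 (0.0350). Chosen after their values were seen, AGO7 (AT1G69440), which cuts transcripts with a microRNA and sets off small RNAs against auxin response factors, rose by 2.08 ± 0.20 (0.0128), and MGL (AT1G64660), which breaks down methionine, by 2.22 ± 0.16 (0.00528). FDH (AT5G14780), formate dehydrogenase, rose by 1.62 ± 0.12 (0.00645), and GAMMA-VPE (AT4G32940), a vacuolar protease, by 0.86 ± 0.11 (0.0293; 0.0517 with the replicate block). MGL passed without each array in turn, AGO7 did not without induced replicate 2 (0.0732) or 3 (0.0842) or uninduced replicate 2 (0.0828) or 3 (0.0927), FDH did not without induced replicate 2 (0.0552) or 3 (0.0540) or uninduced replicate 3 (0.0564), and GAMMA-VPE passed in none of these 6 fits (0.0770 to 0.168).

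The tests of the inducer, of a separate summarization of replicate 1 and of fewer dividing cells were chosen only after the results were seen. The 187 changed genes could reflect the inducer or ATHB8. The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05: the real split called 369 rows, 187 genes and 6 lists, and the highest other counts were 4 rows, 0 genes and 1 list (at most 2010 genes at an unadjusted p under 0.05). The other 3 splits that part all same-numbered pairs, and so mix the treatments, called 0 rows in limma (at most 662 at an unadjusted p under 0.05), and the split with 4 rows kept both replicate 1 arrays together. Of 17 glutathione transferase and xenobiotic genes 0 rose in limma, with 1 higher and 3 lower at an unadjusted p under 0.05. Their median log2 difference was -0.19. This cannot decide on a detoxification response to the inducer, since few modest changes pass this fit. In the simulated data it found 0 of 50 genes changed 1.5-fold and 15 of 50 changed 2-fold. The design holds no line without the transgene, so effects of estrogen and those of ATHB8 cannot be told apart, and both stay open.

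The replicate 1 arrays stood apart from the other 4 on the first component. A wrong treatment label on a replicate 1 array is argued against by the 80 rows called in replicates 2 and 3 alone, of which 100% moved the same way in replicate 1 (95% interval 95.5 to 100). The interval counts rows of the same arrays, which are not independent replicates, so it does not measure the spread between arrays. A separate run of the authors' summarization for these arrays is a candidate explanation, since they share exact values in 12229 rows against at most 23 in any other pair. A difference between the cultures of replicate 1 and the rest was not tested and stays open.

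The mitosis genes lay lower in the induced arrays. A single pair of arrays carrying this is argued against by the 3 same-numbered pairs, in which the list's median lay at or below percentile 0.02 of 10000 matched random lists. The random lists hold genes drawn separately, while the mitosis genes had an estimated correlation of 0.22. These percentiles therefore do not measure how often such a shift arises between cultures. With the estimated correlation camera did not call the list (adjusted p = 0.432). That setting also tests on the 4 residual degrees of freedom, so the correlation alone need not have ended the call. Of the 12 replication genes 10 lay lower as well, though the call of that list ended in most fits that left out an array. Fewer dividing cells in the induced cultures and lower transcript levels in each dividing cell could both give this count. It cannot tell them apart, and both stay open, as no count of cells was analysed here.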
